A study of Homo sapiens with 3 samples.

How the data were processed

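Total RNA from MDA-MB-231 cells depleted of KAP1 and re-expressing wild-type, S473A or S473D KAP1 was extracted with TRIzol and made into libraries by Illumina's protocols, per the labels' protocols. The labels give 3 libraries, 1 for each form of KAP1, and each was placed in its group by its title. The reads were aligned with Bowtie and handled in Partek against genome build hg19, per the submitters' processing notes, while the versions, the gene annotation, the counting rule and any filters are not given in the sources used here. The deposited table holds log2 values of RPKM, read numbers scaled to gene length in kilobases and to library depth, 1 column per library and 1 line per gene symbol, per the file name and the values themselves. Its lowest value in every column is -3.32, the log2 of 0.1, and the deposited values were therefore read as RPKM with 0.1 added before the log. RPKM values were recovered by undoing the log and subtracting 0.1.

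Of the 19076 lines, 27 were left out because spreadsheet software had turned the symbol into a date or because the symbol was repeated, leaving 19049 genes. Genes with a mean of at least 1 RPKM over the 3 libraries were kept, and 175 short RNAs such as small nucleolar RNAs and microRNAs were left out, since their RPKM rests on few reads over a short length, which left 11573 genes. The table holds 0 of the genes encoded by mitochondrial DNA under their usual symbols, so their set was not analysed here. RPKM is relative to all counted reads, so abundant transcripts that take a larger share of one library lower the values of all other genes in it. It also divides by gene length, and a library with a different preference for short or long transcripts keeps that preference in these values.

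The table gives no read counts. The value of 1 read relative to wt was estimated from the ratio most often seen between the values of 1775 low genes, which is 0.875 for S473A and 1.07 for S473D, and the absolute depth from low RPKM values multiplied by transcript length. The estimate, rounded, was 25800000 reads for wt, 29500000 for S473A and 24000000 for S473D. Transcript lengths came from GENCODE release 29, which may not be the lengths used by the authors, and between 45.2% and 46.3% of low values came out as whole reads within 2%, so the depths are estimates and no count model was fitted. Numbers of reads per gene were estimated from these depths and lengths, and exact 95% intervals for ratios of RPKM were computed from them. They cover counting error only and not the spread between cultures.

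The differences S473A minus wt, S473D minus wt and S473D minus S473A were taken on log2(RPKM + 1). With 1 library per group no test of a difference exists, so genes were counted by a fixed size of 2-fold, and counts from counting error alone were simulated in 100 draws. Genes without a GENCODE transcript were drawn there at the median transcript length, which understates the counting error of shorter ones. The design, the gene sets, the alternatives and the rule for named genes were fixed before the data were examined. The rule names TRIM28 and 7 genes of mitochondrial dynamics and p53 response in every library, and per comparison the 10 highest and 10 lowest differences among genes with a mean of at least 5 RPKM, leaving out short RNAs and provisional LOC symbols. It also names up to 2 highest and 2 lowest members of each gene set and up to 5 genes in each direction that step in order through S473A, wt and S473D by at least 1.5-fold per step. Some genes that the rule names are not reported here. For 29 of 35 gene sets, those with at least 5 measured members, the median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentiles describe these libraries and are not p-values. The variance particular to each library was solved from the 3 pairwise variances. The correlation of the differences from wt was set beside one simulated for unchanged groups of equal spread sharing that library.

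Transcript length and GC content came from 1 GENCODE transcript per gene symbol in the GRCh38 build, the longest with a RefSeq record or otherwise the longest, used for those properties alone and for no coordinates, and 10782 genes (93.2%) had one. After the data were seen, alternatives were added in which smooth trends on length and GC content (lowess, fraction 0.2, 2 rounds) were removed from the differences of genes and gene sets, and in which random lists were drawn from the 20 nearest genes in expression, length and GC content. Removing the trends kept the overall median of the differences. A further 17 gene families were described after the data were seen. The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter or a minimum mean of 5 RPKM, differences centred on their median, libraries scaled by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end), short RNAs kept, and random lists not matched on expression.

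The steps were tested on simulated data. With 200 of 11566 genes changed 4-fold between S473D and wt, 94% passed 2-fold in the right direction and 1 unchanged gene did. Of 100 unshifted random sets 5 lay outside the central 95%. A set of short unchanged genes under a planted length trend lay at percentile 100 of expression-matched lists and 33.2 once length and GC content were matched. Over 10589 unchanged genes, removing the planted trend moved the rank correlation of the differences with length from -0.95 to 0.01. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.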

Results

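RNA was sequenced from MDA-MB-231 cells, an established human breast cancer line of the basal-like type, whose own KAP1 had been depleted with a short hairpin RNA. KAP1, encoded by TRIM28, is a corepressor that KRAB zinc finger proteins bring to chromatin. The cells carried a re-expressed KAP1 in 1 of 3 forms, and each form gave 1 library. The wild-type form (wt) keeps the serine under study, which can be phosphorylated. In S473A that serine is replaced by alanine, which cannot be phosphorylated, and in S473D by aspartate, whose negative charge imitates a phosphorylated serine. The comparisons ask how the transcript levels of cells with each substitution differ from those of cells with wild-type KAP1 and from each other. The deposited table gives log2 values of RPKM, read numbers scaled to gene model length in kilobases and to library depth, with 0.1 added before the log, for 19076 gene entries. Estimated from the steps between low values, the depth was 25800000 counted reads for wt, 29500000 for S473A and 24000000 for S473D. Levels of at least 1 RPKM were reached by 11793 genes in wt, 11766 in S473A and 11651 in S473D. With 1 library per group there is no replicate error, so no p-value is given and each difference describes a pair of libraries. Differences are on the log2(RPKM + 1) scale, which understates those of low genes, and cover 11573 genes with a mean of at least 1 RPKM over the 3 libraries. Intervals beside ratios of RPKM are exact 95% intervals for counting error only.

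TRIM28, the gene that was depleted and put back, was present in all 3 libraries, at 28.7 RPKM in wt, 32.3 in S473A and 25.6 in S473D. The log2 difference from wt was 0.16 for S473A and -0.16 for S473D, the latter -0.06 once the differences were centred on their median. The values do not separate endogenous from re-expressed transcript. Genes of mitochondrial fusion and fission, fixed for inspection before the data were examined, stayed near wt with 1 exception. The fusion GTPase gene MFN1 stood at 11.3 RPKM in wt, 9.97 in S473A and 10.3 in S473D, its partner MFN2 at 23.3, 24.2 and 21.1, and OPA1, which fuses inner membranes, at 30.3, 29.9 and 28.4. DNM1L, the fission GTPase gene, stood at 21.3 RPKM in wt, 22.4 in S473A and 20.2 in S473D. FIS1, which encodes an outer-membrane protein of the fission machinery, was 1.77-fold higher in S473D than in wt (64.9 against 36.7 RPKM, interval 1.61 to 1.95), a log2 difference of 0.81 that was 0.29 once trends on transcript length and GC content were removed. The p53 target CDKN1A, a cell cycle inhibitor gene, stood at 32.2 RPKM in wt, 34.1 in S473A and 32.0 in S473D, and the stress gene GADD45A at 35.9, 35.7 and 37.6. As sets, 15 fusion genes had a median difference of 0.05 between S473D and wt and 13 fission genes -0.08, at percentiles 75.9 and 51.4 of random gene lists matched on expression. Between S473A and wt those medians were -0.01 and 0.00, at percentiles 25 and 40.9.

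**Figure D1:**
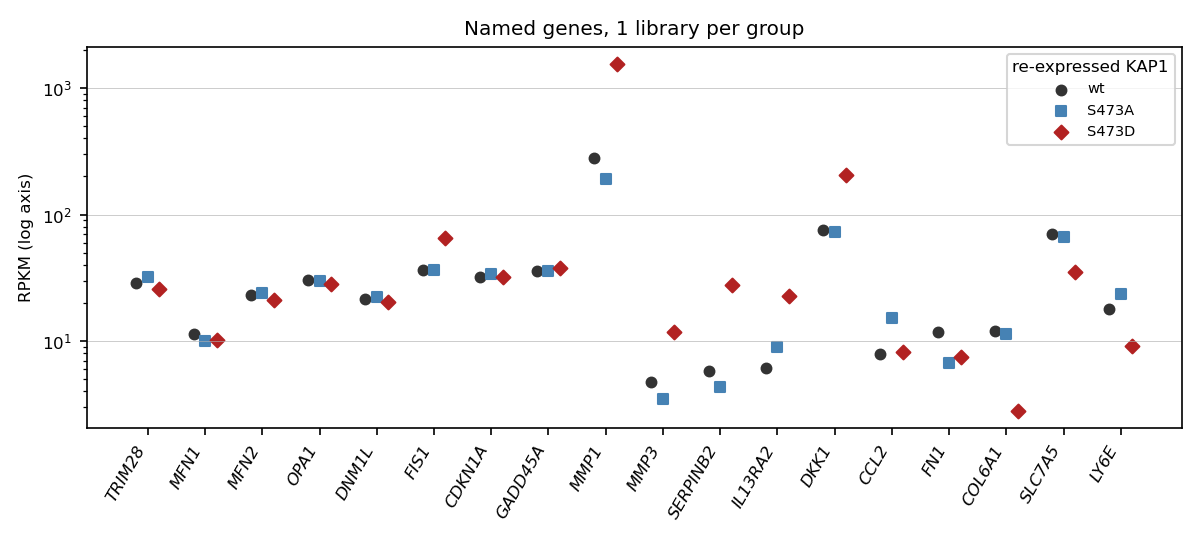
RPKM on a log axis of the genes fixed beforehand and of genes named for the size of their differences, with 1 point per library (circles wt, squares S473A, diamonds S473D) and no error bars, since each group has 1 library. MMP1 stands at 279 RPKM in wt, 191 in S473A and 1541 in S473D, while TRIM28 lies between 25.6 and 32.3.

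Cells with the alanine form differed little from cells with wild-type KAP1. The genes named first are among the 20 most extreme differences and were picked for their size alone. CCL2, a monocyte-attracting chemokine gene, was 1.95-fold higher in S473A (15.3 against 7.84 RPKM, interval 1.60 to 2.37), and IL13RA2, an interleukin-13 receptor gene, 1.47-fold (8.97 against 6.10, interval 1.24 to 1.74). FN1, which encodes fibronectin, was 1.76-fold higher in wt (11.7 against 6.67 RPKM, interval 1.65 to 1.87). The collagenase gene MMP1 was 1.46-fold higher in wt (279 against 191 RPKM, interval 1.42 to 1.5), and the stromelysin gene MMP3 1.36-fold (4.75 against 3.48, interval 1.13 to 1.65). Further genes higher in S473A were the histone genes HIST1H4H and HIST1H2AC (0.47 and 0.41), ZNF414 (0.43) and SNHG9 (0.39, with a counting interval of 0.991 to 1.83 for its RPKM ratio that includes 1). Further genes lower in S473A were LINC00467 (-0.38) and C15orf48 (-0.36). Some of the 20 genes with the most extreme differences have near-identical copies or share exons with neighbours, so their values are uncertain. These were the glutathione transferase pair GSTT2B and GSTT2, which went opposite ways (0.86 and -0.66), and BCYRN1 (0.72), RBM14-RBM4 (0.47), CBWD3 (0.41), GPR89C (-0.67), SPANXA1 (-0.61), ANP32D (-0.61) and SMN1 (-0.35).

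None of these named genes reached a 2-fold difference on the log2(RPKM + 1) scale. Of the 11573 genes, 2 did, and both are low and uncertain genes named here because the count is so small. The readthrough transcript TGIF2-C20orf24 was higher in S473A (3.72 against 1.33 RPKM), and MTRNR2L9, a nuclear copy of mitochondrial ribosomal RNA, was lower (0.199 against 2.35 RPKM). Counting error alone, simulated at the estimated depths, gave 0.21 genes on average and at most 2 in 100 draws. Only 1 of the 2 genes had a matched transcript, and the other was drawn at the median transcript length. Its counting error is understated if its transcript is shorter. Among 3371 genes with a mean of at least 20 RPKM the differences had an SD of 0.06 where counting error alone gives 0.04, a variance ratio of 2.30. The count of 2 moved to 14 with a pseudocount of 0.1 and to 0 among genes with a mean of at least 5 RPKM.

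Small differences between S473A and wt ran in the same direction in 4 of the gene sets fixed beforehand. Of 29 interferon-stimulated genes 21 were lower in S473A (median -0.08), among them IFIT2 (-0.38) and IFIT1 (-0.37), and the set lay at percentile 0.01 of matched random lists. Of 26 NF-kB targets, cytokines and chemokines 20 were lower (median -0.08, percentile 0.00), with CCL20 at -0.41 and CXCL1 at -0.30 against CCL2 at 0.88. Of 28 hypoxia genes 23 were lower (median -0.09, percentile 0.00), including the collagen-crosslinking enzyme gene LOX (-0.20) and ALDOC (-0.18). Of 33 genes of the ATF4 and unfolded protein response 23 were lower (median -0.06, percentile 0.00), including CHAC1 (-0.45) and DDIT4 (-0.23). In the other direction 17 of 21 replication-dependent histone genes were higher in S473A (median 0.13, percentile 100), although HIST1H2BC (-0.40) and HIST2H2BE (-0.34) were lower. None of the members of these sets was 2-fold apart. The ATF4 and NF-kB sets also had medians below wt in S473D (-0.19 and -0.29). Between S473D and S473A they lay at percentiles 36.6 and 12.6 of expression-matched lists (82.2 and 0.23 with length and GC content matched). For these 2 sets a departure of the shared wt library cannot be told apart. Interferon-stimulated genes were instead above wt in S473D (0.20), and hypoxia genes lay at percentile 59.3 there. With 29 sets compared, 1.45 would lie outside the central 95% of random lists by chance if genes within a set varied independently, and 5 did. All of these stayed outside when the random lists were also matched on transcript length and GC content, where glycolysis (median -0.02) joined them at percentile 2.47. The number depends on the filter, since 9 lay outside among genes with a mean of at least 5 RPKM, 2 above and 7 below. Those joining were mesenchymal (percentile 0.07), luminal breast epithelium (0.64) and epithelial genes (1.29) below and NRF2 targets (99.4) above. The ribosomal protein and oxidative phosphorylation sets had medians of 0.00, and KAP1 with its corepressor partners 0.01 (percentile 67.0).

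Cells with the aspartate form stood apart from wild-type cells in many more genes. MMP1 had the largest difference of the named genes, 5.52-fold higher in S473D (1541 against 279 RPKM, interval 5.42 to 5.62). SERPINB2, which encodes the plasminogen activator inhibitor PAI-2, was 4.81-fold higher (27.8 against 5.79 RPKM, interval 4.26 to 5.44). IL13RA2 was 3.73-fold higher (22.7 against 6.10 RPKM, interval 3.19 to 4.35), and DKK1, a secreted Wnt antagonist gene, 2.71-fold (206 against 75.9 RPKM, interval 2.60 to 2.82). LY96, which encodes the TLR4 co-receptor MD-2, was 3.50-fold higher (12.9 against 3.70 RPKM, interval 2.58 to 4.76). CCDC167 (1.54 on the log2 scale), the noncoding FLJ22447 (1.45) and the ribosomal protein gene RPL9 (1.44) followed, and the testis-antigen genes SPANXA2 (1.87) and SPANXE (1.46) are uncertain because family members are near-identical in sequence.

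COL6A1, a collagen VI chain gene, led the genes that were lower in S473D, 4.31-fold higher in wt (12.1 against 2.80 RPKM, interval 3.78 to 4.91). The sulfotransferase gene CHST15 (7.88 in wt against 3.19 RPKM, log2 difference -1.08) and the prolyl hydroxylase gene LEPREL1 (29.1 against 13.0, -1.11) were also lower in S473D. CAMK2N2 (13.1 against 6.09 RPKM) was lower by just under 2-fold on the log2(RPKM + 1) scale (-0.995). The pseudogene MSTO2P (-1.03) was lower too, but is uncertain because it resembles MSTO1. SLC7A5, an amino acid transporter gene, was at 70.05 RPKM in wt and 34.8 in S473D (-0.99). BCL3 (-0.98), FOSL2 (-0.94), NCK2 (-0.92) and the ephrin gene EFNB1 (-0.92) were among the 10 lowest without reaching 2-fold on the log2(RPKM + 1) scale.

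Between S473D and wt 126 genes were at least 2-fold apart, 115 higher and 11 lower in S473D. Counting error alone gave 0.25 such genes on average and at most 2 in 100 draws, and among genes with at least 20 RPKM the variance of the differences was 107 times that of counting error. The median difference of all genes was -0.10, and scaling the libraries to remove that shift gave 205 genes, 197 higher and 8 lower. Removing smooth trends on transcript length and GC content, a step added after the data were seen, turned the split to 21 higher and 37 lower of 10782 genes with a matched transcript. That step kept the overall median difference, at -0.11, which favours lower genes in the split. Of the 106 genes that were 2-fold apart and had a matched transcript, 23 were still apart in the same direction after that step. MMP1 (2.46 before, 2.16 after), SERPINB2 (2.09 and 1.77), IL13RA2 (1.74 and 1.16), DKK1 (1.43 and 1.08) and COL6A1 (-1.78 and -1.51) were among them, and LY96 (1.57 and 0.50) and RPL9 (1.44 and 0.66) were not.

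**Figure D2:**
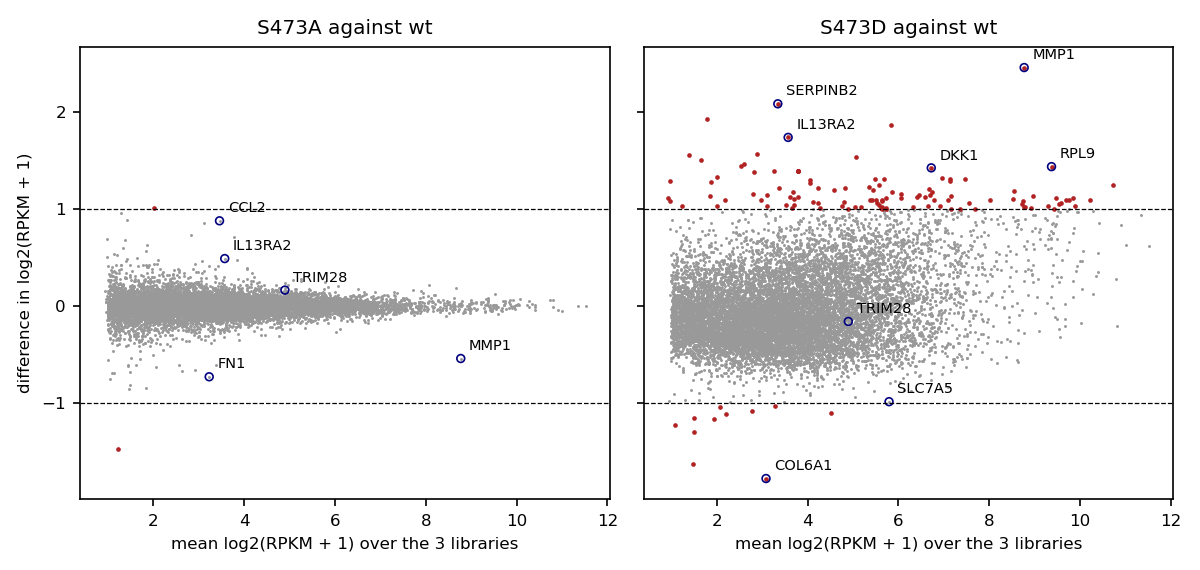
Difference in log2(RPKM + 1) of each of 11573 genes (1 point per gene) against its mean log2(RPKM + 1) over the 3 libraries, for S473A against wt on the left and S473D against wt on the right. Dashed lines mark 2-fold and points past them are red, 2 genes for S473A and 126 for S473D, and named genes are circled.

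Among the sets fixed beforehand with at least 5 measured members, those of ribosomal proteins and oxidative phosphorylation had the highest medians in S473D against wt. Of 78 cytosolic ribosomal protein genes 76 were higher and 14 at least 2-fold higher (median 0.81), with RPL9 at 1.44, RPS18 at 1.25, RPS3 at -0.02 and RPL28 at -0.13. These genes took 13.8% of summed RPKM in wt and S473A and 19.9% in S473D, and many have processed pseudogenes with which reads can be shared. Of 77 nuclear genes of oxidative phosphorylation 71 were higher and 9 at least 2-fold higher (median 0.67), with NDUFA4 and COX7B both at 1.31 against SDHA at -0.32 and ATP5D at -0.40. Of 76 mitochondrial ribosomal protein genes 71 were higher and 1, MRPS23 (1.10), at least 2-fold higher (median 0.54). The 3 sets lay at percentile 100 of random lists matched on expression and of lists matched also on transcript length and GC content. With the trends removed their medians were 0.32, 0.21 and 0.13, against -0.11 for all genes. For oxidative phosphorylation, 62 of the 77 genes had a matched transcript. Its percentile with length and GC content matched and its median with the trends removed rest on those.

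Interferon-stimulated genes were also higher in S473D, 19 of 29 with a median of 0.20 (percentile 99.99). ISG15 (70.2 against 32.2 RPKM, 2.18-fold, interval 1.96 to 2.42) and IFI44 (0.95) led them, while OAS3 was at -0.58. With the trends removed the median was 0.03, against -0.11 for all genes. With length and GC content matched the set stayed at percentile 99.99. Of 21 replication-dependent histone genes 16 were higher (median 0.31, percentile 100), with HIST1H2BK at 0.84, but the median turned to -0.23 with the trends removed. Of 17 genes that host small nucleolar RNAs or are long nuclear RNAs 12 were higher (median 0.50, percentile 99.9, or 0.16 with the trends removed), with SNHG8 at 0.99 and NEAT1 at -0.88. The 354 genes with ZNF symbols, most of them the zinc finger family whose KRAB members bind KAP1, had a median of -0.04, below 0 as deposited but above both the median of all genes and matched random lists (-0.18 to -0.11). Among genes with a mean of at least 5 RPKM the family's median was -0.12, below the -0.08 of all such genes and at percentile 62.7 of matched lists. In that family ZNF593 (1.01) and ZNF542 (1.04) were 2-fold higher and ZNF385A was at -0.91.

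Mesenchymal genes, YAP and TEAD targets and genes of cholesterol synthesis lay below wt in S473D. Of 23 mesenchymal genes 17 were lower (median -0.39, percentile 0.00), including COL6A1 and the gelatinase gene MMP9 (2.70 RPKM in wt, 0.660 in S473D), although MMP1 (2.46) and S100A4 (1.07) in the same set were over 2-fold higher, and with the trends removed the median was -0.24 against -0.11 for all genes. Of 22 YAP and TEAD targets 17 were lower (median -0.33, percentile 0.05, or -0.17 with the trends removed), including ASAP1 (-0.80) and CRIM1 (-0.71), against ANKRD1 at 1.25. NF-kB targets, cytokines and chemokines went both ways, 15 of 26 lower and 11 higher, with a median of -0.29 (percentile 0.55) and a mean of -0.06, and with CSF1 at -0.89 and TNFAIP2 at -0.61 but BCL2A1 at 0.90 and IL1A at 0.80. Of 26 cholesterol biosynthesis genes 19 were lower (median -0.24, percentile 0.87), including the regulator gene SREBF1 (-0.56), and with the trends removed the median was -0.27. Serum response and immediate early genes had a median of -0.22 (percentile 2.41), with FOSL2 at -0.94 and SPRY4 at -0.82. Of 34 genes for KAP1 and its corepressor partners 24 were lower and 10 higher (median -0.22, percentile 0.94), with MTA1 at -0.49 and MORC2 at -0.48, and -0.15 with the trends removed. Against random lists not matched on expression the cholesterol (percentile 2.59), serum response (6.49) and KAP1 partner sets (4.13) lay inside the central 95%.

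In all, 13 of 29 sets lay outside the central 95% of expression-matched lists, against 1.45 expected by chance if genes within a set varied independently. With lists matched also on transcript length and GC content, 10 did. The serum response set (percentile 33.3), KAP1 with its partners (12.4), the histone genes (94.8) and the small nucleolar RNA hosts (96.7) no longer stood outside, and 8 luminal breast epithelium genes (median 0.09) moved from percentile 78.9 to 98.8, with KRT19 at 0.89.

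Sets inside the central 95% of expression-matched lists in S473D against wt included the metabolic and cell cycle groups. Glycolysis had a median of -0.14 (percentile 5.99), with PGK1 at 0.73 and PFKFB3 at -0.60, and the tricarboxylic acid cycle -0.08 (percentile 21.4), with MDH1 at 0.89 and CS at -0.55. S phase genes had a median of -0.11 (percentile 17.0), with PCNA at 0.95, and G2 and M phase genes 0.04 (percentile 50.4), with CDK1 at 0.90 and MKI67 at -0.64. AMPK subunits and energy-stress genes stood at -0.24 (percentile 8.61), p53 and DNA damage response targets at 0.03 (percentile 91.2), mitophagy and autophagy genes at 0.00 (percentile 78.9) and NRF2 targets at -0.09 (percentile 36.0). The medians were -0.06 for hypoxia genes (percentile 59.3), -0.19 for the ATF4 and unfolded protein response (percentile 3.24), -0.17 for imprinted genes (percentile 21.6) and -0.13 for epithelial genes (percentile 28.8). The basal breast epithelium set had a median of -0.29 (percentile 4.86, or 45.2 with length and GC content matched). Some of these medians moved with the trends removed, against -0.11 for all genes. They were then -0.09 for AMPK and energy-stress genes, -0.11 for p53 targets, -0.15 for G2 and M phase genes and -0.08 for basal genes. Among 4 measured cancer-testis genes the median was 0.36, with XAGE1A at 1.39, whose near-identical copies carry the same value.

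**Figure D3:**
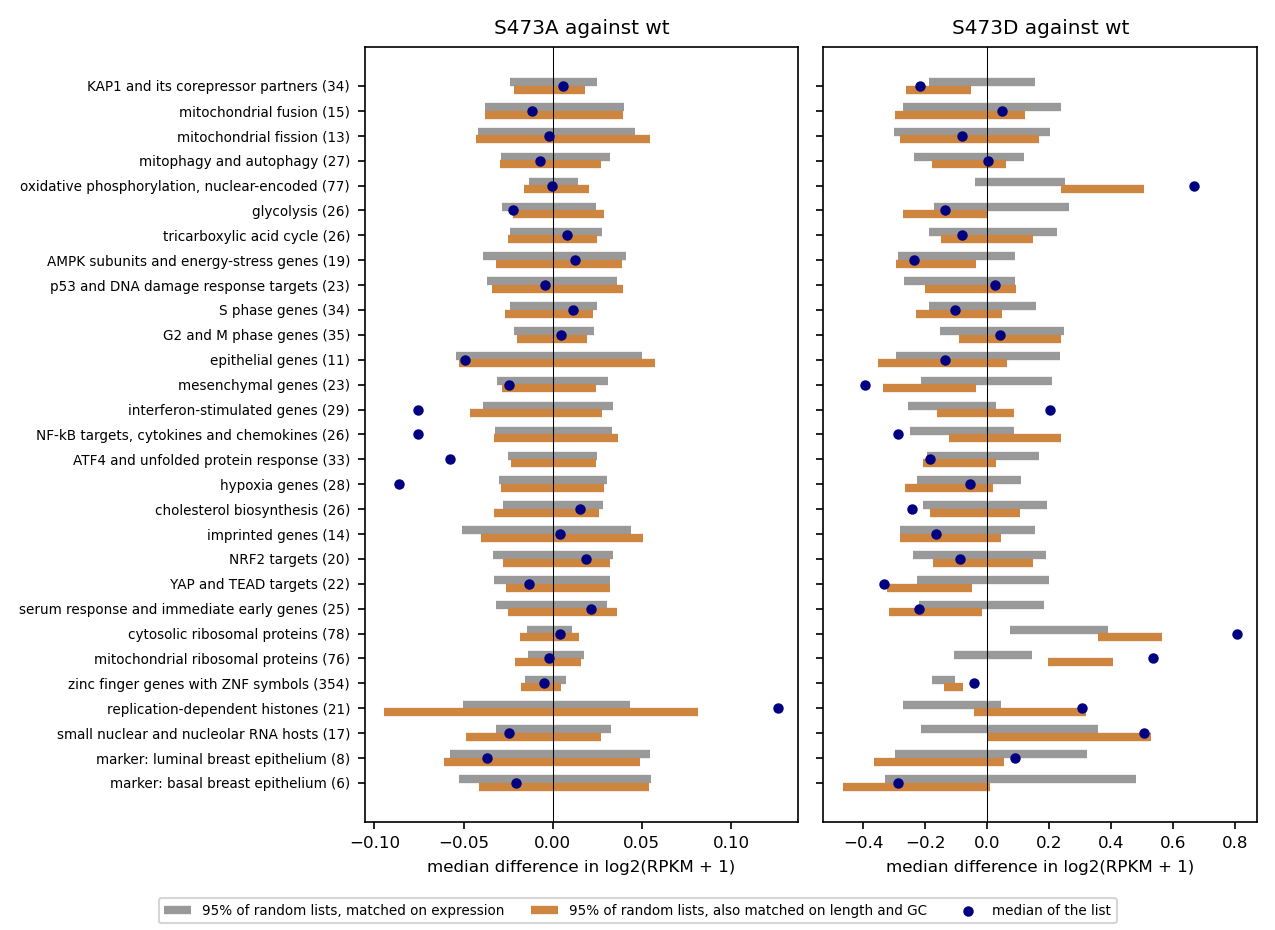
Median difference in log2(RPKM + 1) of each of 29 gene sets fixed before the data were examined (points, number of measured genes in parentheses), for S473A against wt on the left and S473D against wt on the right, on different horizontal scales. Grey bars span the central 95% of random lists matched on expression and brown bars those matched also on transcript length and GC content. In S473D the cytosolic ribosomal protein (0.81) and oxidative phosphorylation (0.67) medians lie beyond both bars.

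Differences between S473D and wt followed transcript length. Genes in the shortest decile of transcripts (median 996 bases) had a median difference of 0.37 and those in the longest decile (median 9146 bases) -0.27. Across genes, which are not independent replicates, Spearman's rho was -0.44 with length and -0.26 with GC content, against -0.01 and 0.08 between S473A and wt. The 2 trends together took up 38.7% of the variance of the S473D differences and 1.22% of those of S473A. The genes at least 2-fold higher in S473D had a median transcript of 943 bases, against 3240 for all genes with a matched transcript, and 24 of the 115 belong to the ribosomal protein and oxidative phosphorylation sets.

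**Figure D4:**
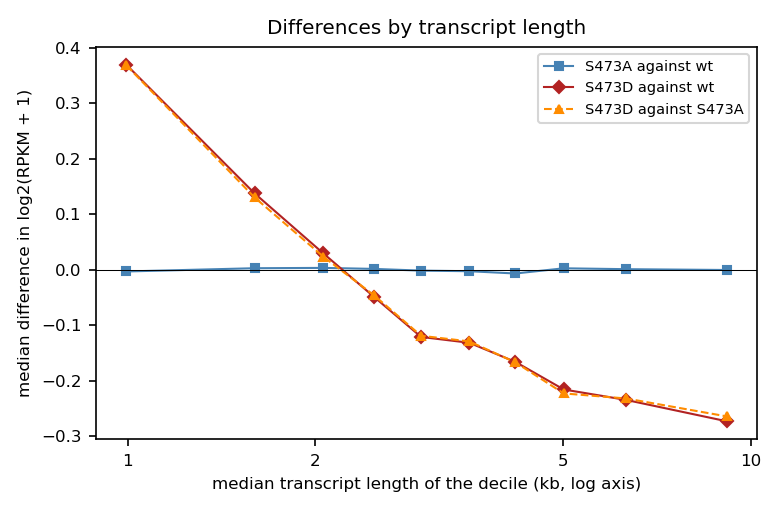
Median difference in log2(RPKM + 1) of genes in each decile of transcript length (log axis, in kilobases), for the 3 pairs of libraries. The S473D curves run from 0.37 in the shortest decile to -0.27 against wt in the longest, and the S473A curve stays within 0.01 of 0.

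Set directly against the alanine form, the aspartate form showed many of the same genes. Such an overlap was fixed in advance, since both comparisons share the S473D library and wt and S473A are close. MMP1 was 8.05-fold higher in S473D (interval 7.90 to 8.22) and SERPINB2 6.42-fold (27.8 against 4.34 RPKM, interval 5.63 to 7.32). The phosphatase gene PTPRR was 3.54-fold higher (13.1 against 3.69 RPKM, interval 3.15 to 3.99), MMP3 3.4-fold (11.8 against 3.48, interval 2.89 to 4.0) and DKK1 2.81-fold (interval 2.70 to 2.92). LINC00493 (1.46) and RPL9 (1.36) were also among the 10 highest, together with SPANXA1 (1.83), SPANXA2 (1.68) and SPANXE (1.5), the last 3 uncertain for their near-identical copies. COL6A1 was 4.03-fold higher in S473A (interval 3.54 to 4.59). LY6E, an interferon-inducible membrane protein gene, was 2.59-fold higher in S473A (23.5 against 9.09 RPKM, interval 2.24 to 2.98), with 17.8 RPKM in wt. CHST15 (-1.04), LEPREL1 (-1.04), EFNB1 (-1.003), MSTO2P (-1.003), CAMK2N2 (-0.96), the glutamine synthetase gene GLUL (-0.96), BCL3 (-0.95) and SLC7A5 (-0.90) completed the 10 lowest.

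In that pair 131 genes were at least 2-fold apart, 116 higher and 15 lower in S473D, where counting error alone gave 0.22. The sets outside the central 95% of expression-matched lists numbered 12, 7 above and 5 below. Above were cytosolic ribosomal proteins (median 0.82), oxidative phosphorylation (0.67), mitochondrial ribosomal proteins (0.51), small nucleolar RNA hosts (0.46), interferon-stimulated genes (0.30), histones (0.29) and ZNF genes (-0.04). Below were mesenchymal genes (-0.32), YAP and TEAD targets (-0.30), serum response genes (-0.28), cholesterol biosynthesis (-0.26) and KAP1 with its partners (-0.23). ISG15 was 2.46-fold higher in S473D than in S473A (interval 2.22 to 2.74). With length and GC content also matched, 8 sets lay outside, 6 of the 12 no longer among them. Those were mesenchymal genes (percentile 4.20), YAP and TEAD targets (5.5), serum response genes (18.5), KAP1 with its partners (15.5), histones (82.4) and small nucleolar RNA hosts (97.2), while NF-kB targets (0.23) and hypoxia genes (98.9) joined. With the 2 trends removed, 18 genes were higher and 46 lower among 10782 genes with a matched transcript. Of the 131 genes 112 had a matched transcript, and 23 were still apart. Removing the trends also turned the histone median to -0.28 and left the interferon-stimulated median at 0.05. It left cytosolic ribosomal proteins at 0.31, oxidative phosphorylation at 0.21, mitochondrial ribosomal proteins at 0.12 and small nucleolar RNA hosts at 0.17, and of the sets below, mesenchymal genes at -0.18 and YAP and TEAD targets at -0.15, against -0.10 for all genes. KAP1 with its partners lay inside the central 95% of lists not matched on expression (percentile 2.78). The ZNF genes lay at percentile 82.9 among genes with a mean of at least 5 RPKM.

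The 3 libraries were not evenly spaced. Differences had an SD of 0.10 between S473A and wt, 0.37 between S473D and wt and 0.37 between S473D and S473A. Splitting these into parts particular to each library gave a variance of 0.00493 for wt, 0.00563 for S473A and 0.133 for S473D. S473D lay at least 2-fold above both other libraries in 93 genes and below both in 8, where unchanged groups sharing that library gave 0 and independent lists would share 1.15 and 0.0143. The simulated value leaves out real differences and the other leaves out the shared library, and since wt and S473A are close to each other, a large overlap was fixed in advance and is not read as a finding. Part of that overlap may come from the shared S473D library, which cannot be divided. Across genes, the differences of S473A and S473D from wt had a correlation of 0.129, where unchanged groups of equal spread sharing that wt library would give 0.50. Their covariance was 0.00493, against 0.00527 simulated from the shared library alone, and they had the same sign in 52.8% of genes against 66.8% simulated. The simulation gives all 3 libraries the spread seen between S473A and wt, while S473D varied far more. That larger spread by itself lowers the correlation and the same-sign share, so neither is read as a shortfall. The covariance is by construction the variance particular to wt, and the simulated value rests on the difference between S473A and wt, so setting one beside the other cannot detect a difference shared by S473A and S473D. Part of the covariance may come from the shared wt library, which cannot be divided, and a shared difference stays open.

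Few genes stepped in order from the alanine form through wild type to the aspartate form. Of the 11573 genes 2 were at least 1.5-fold higher at both steps, the antisense transcript PCNA-AS1 (0.869, 2.37 and 6.40 RPKM in S473A, wt and S473D) and SPANXA1 (4.90, 8.02 and 19.97 RPKM), and 0 were lower at both steps. For comparison 2 genes had S473A in the middle and 0 had S473D. PCNA-AS1 overlaps PCNA and SPANXA1 has near-identical copies, so both are uncertain. With the trends on length and GC content removed 1 gene, SPANXA1, was higher and 2 were lower at both steps, PCNA-AS1 being left out there for want of a matched transcript. MMP1, MMP3 and SERPINB2 had the same order, but S473A lay below wt by less than 1.5-fold in each of them (-0.54, -0.36 and -0.35 on the log2 scale).

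Markers of other cell types were low. Summed RPKM of the fibroblast markers was 3.76 in wt, 3.49 in S473A and 3.33 in S473D, and that of hepatocyte markers 1.56, 1.40 and 1.09. Neural markers summed to 31.2, 29.2 and 31.0 RPKM, mostly from TUBB3, and haematopoietic markers to 52.1, 53.3 and 38.4, mostly from CD68. Luminal markers summed to 374, 362 and 454 RPKM and basal markers to 372, 373 and 328.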

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

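Removal of the trends on transcript length and GC content and random lists matched on those properties were chosen only after the results had been seen, and the other alternatives before. No paired analysis was possible because each group has 1 library and no test was run. No named gene past 2-fold changed sign under any alternative run for it. Of the sets outside the central 95%, the median of the replication-dependent histones changed sign with the trends removed, to -0.23 between S473D and wt and -0.28 between S473D and S473A. Between S473A and wt the 2 genes at least 2-fold apart became 14 with a pseudocount of 0.1 (5 higher, 9 lower), 7 with 0.5 (3 higher, 4 lower) and 19 with short RNAs kept (9 higher, 10 lower), 0 (0 higher, 0 lower) at a mean of at least 5 RPKM, and 1 (0 higher) with the trends removed, and those lower became 2 with no filter. Between S473D and wt the 126 genes became 205 with a pseudocount of 0.1 (46 lower), 205 after centring (197 higher), 218 after trimmed-mean scaling (210 higher) and 58 with the trends removed (21 higher, 37 lower), and the 11 lower became 25 with a pseudocount of 0.5, 4 at a mean of at least 5 RPKM and 20 with short RNAs kept. Between S473D and S473A the 131 genes became 218 with a pseudocount of 0.1 (54 lower), 217 after centring (209 higher, 8 lower), 224 after trimmed-mean scaling (215 higher, 9 lower) and 64 with the trends removed (18 higher, 46 lower), and the 15 lower became 28 with a pseudocount of 0.5, 6 at a mean of at least 5 RPKM and 26 with short RNAs kept. The correlation of the differences of S473A and S473D from wt, 0.129, was 0.154 with no filter, 0.105 at a mean of at least 5 RPKM and 0.183 with the trends removed. Genes stepping in order numbered 6 with a pseudocount of 0.1 (4 higher and 2 lower at each step), 1 at a mean of at least 5 RPKM and 3 with the trends removed (1 higher, 2 lower), against 2, both higher. Smaller pseudocounts and short RNAs add genes by construction, since they let few reads give a large log ratio, and a higher minimum leaves fewer genes. Removing the trends kept the overall median and also left out genes without a matched transcript. Of the genes at least 2-fold apart, 1 of 2 had one between S473A and wt, and it stayed apart. For S473D that held for 106 of 126 against wt and 112 of 131 against S473A, so not all of those changes come from the trends. For the correlation, the histone medians and the trends the cause was not tested. The sets outside the central 95%, 30 over the 3 comparisons, numbered 26 to 32 under the alternatives fixed beforehand and 24 with length and GC content matched. Between S473A and wt the 5 became 9 at a mean of at least 5 RPKM, and between S473D and wt the 13 became 10 with lists not matched on expression, where the cholesterol, serum response and KAP1 partner sets lay inside. Depth limits low genes most, and with 1 library per group neither depth nor any of these alternatives measures the spread between cultures.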

Other observations

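The gene families described first, the trends fitted without the ribosomal protein and oxidative phosphorylation genes, the test of both trends as the whole cause, and both tests on MMP1, MMP3 and SERPINB2 were chosen only after the results had been seen. The tests of length alone, GC content alone, counting error and matched lists for ribosomal protein genes were chosen before.

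In S473D 7 of the 17 added families lay outside the central 95% of expression-matched lists and 3 with length and GC content matched. By chance 0.85 would if genes within a family varied independently. Some families share members with the fixed sets, such as MMP1, MMP9 and COL6A1 with the mesenchymal genes. They are therefore not separate evidence from those sets. Of 37 proteasome subunit genes 32 were higher (median 0.45), and they stayed above random lists matched on expression (percentile 99.85) and on length and GC content as well (99.73). Of 22 genes of mitochondrial protein import (TOMM and TIMM) 17 were higher (median 0.38, percentiles 99.68 and 97.95). Of 21 spliceosomal Sm and LSM genes 19 were higher (median 0.42), at percentile 99.07 of expression-matched lists and inside the central 95% with length and GC content matched (73.2). All 6 SPANX genes were higher (median 0.99), which is uncertain because they share reads. Of 19 semaphorin and ephrin genes 16 were lower (median -0.32), of 8 laminin genes 7 (median -0.41) and of 12 collagen genes 10 (median -0.32). Those 3 families lay at percentiles 0.57, 0.30 and 1.45 of expression-matched lists and 5.63, 20.7 and 63.4 with length and GC content matched. Solute carriers (-0.12), translation initiation factors (0.02), heat shock families (-0.06), RAB small GTPases (-0.10), integrins (-0.20), serpins (0.18), keratins (0.10), V-ATPase subunits (0.14), chemokines (0.10) and matrix metalloproteinases (-0.10) lay inside the central 95% of expression-matched lists.

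In S473A 4 of the 17 families lay below wt by small amounts and outside the central 95% of expression-matched lists. The same 0.85 would by chance, but the families were described after the data were seen. MMP1 and MMP3 were already among the 10 lowest genes, and some members also belong to the fixed sets. Matrix metalloproteinases had a median of -0.12 (percentile 0.40, or 0.14 with length and GC content matched), C-X-C and C-C chemokines -0.12 (0.70, or 2.43), keratins -0.08 (0.48, or 2.70, which is inside) and serpins -0.07 (0.67, or 0.85). These families hold 6, 5, 6 and 9 measured genes. With length and GC content matched, collagens (median -0.04, percentile 0.70), laminins (-0.05, 1.06) and integrins (-0.04, 2.04) also lay outside.

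S473D stood apart from both other libraries. The tables argue against counting error, since the variance of the S473D minus wt differences at 20 RPKM or more was 107 times the counting variance. Removing the fitted trend on GC content alone left 97 genes 2-fold apart, against 106 before (0.915). These are counts, and the genes after need not be those before. That trend took up 5.64% of the variance, so as fitted it makes up little of the difference. Its decile medians ran only from 0.05 to -0.20, too little to bring most such genes below 2-fold. The counts therefore do not test GC content as a cause. The fitted trends on length and GC content together do not make up the whole difference. The SD of the S473D differences was still 2.92 times that of S473A with both trends removed (3.62 times before). A length or GC bias that smooth trends on 1 transcript per gene miss would remain in that SD, so such a bias is not excluded. Length alone stays open as a large part, since removing its trend gave a count of 65 against 106 before (0.613). That ratio lies between the bounds of 0.5 and 0.8 set beforehand, and these counts too need not hold the same genes. A preference for short transcripts in the preparation of that library or degraded RNA may lie behind the trend, and so may an effect of the aspartate form, and with 1 library per group both stay open.

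Ribosomal protein genes were higher in S473D. Their median lay at percentile 100 of lists matched on expression, length and GC content, but the match was not exact. The matched genes were somewhat less expressed (mean log2 level 8.61 against 9.37), longer (1098 against 994 bases) and higher in GC content (51.5% against 50.1%). Shorter transcripts and lower GC content went with higher values in S473D. So did high expression, since lists matched on expression alone had a median of 0.20, against -0.10 for all genes. Part of the excess may therefore come from this mismatch. With trends fitted on the other genes removed, the median was 0.37 (0.81 before) against -0.11 for those genes. Of 78 members 73 lay above -0.11, so short length and GC content as measured here do not account for all of it. The other genes were not matched on expression, so this gap may overstate the excess. A feature that these transcripts share beyond length and GC content, reads shared with their pseudogenes, or a concerted difference in their transcript levels may be behind the rest, and none of these was tested.

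MMP1, MMP3 and SERPINB2 were lower in S473A and higher in S473D than in wt. Of their families, matrix metalloproteinases were mostly lower in S473D (4 of 6, median -0.10, percentile 35.4) and serpins mostly higher (7 of 9, median 0.18, percentile 94.7), both inside the central 95% of expression-matched lists. The median S473D difference of the 3 genes was 1.77 with both trends removed (2.09 before), the lowest being 0.90. The trends are small beside these differences, with decile medians from 0.37 to -0.27 for length and 0.05 to -0.20 for GC content. Their removal could not have taken the differences away, so it does not test length or GC content as a cause. The tables argue against fibroblasts among the S473D cells, whose marker sum differed by -0.43 RPKM between S473D and wt while MMP1 differed by 1262 RPKM. The 3 genes were picked for this order, and the step from wt to S473A was under 1.5-fold in each. An effect of the KAP1 form and variation between cultures or clones both stay open, since neither can be tested with 1 library per group.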
